A study of Caenorhabditis elegans with 2 samples.

How the data were processed

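Chromatin was precipitated with an antibody against GFP from whole young adult worms whose hmg-20 gene carried an EGFP tag, in 2 biological replicates of 1 group, per the labels. The labels give sonication as the fragmentation method. The aligner, the peak caller and their versions are not given in the sources used here, and the control library named in the labels was not analysed here. The read depth is unknown, since peak lists give no totals. No limit or interval below was computed from depth, although which regions pass the threshold can depend on it. Intervals of shares cover counting error only.

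Each replicate has a ranked peak list and a thresholded one, called per replicate, and the whole series has 2 ranked and 2 thresholded lists derived from both replicates, per the file descriptions deposited with the data. The deposited score column is the scaled irreproducible discovery rate (IDR) of a peak, and the signal column is the authors' peak height, whose scale the files do not state. The deposited −log10 columns hold the q-value and the IDR. In the thresholded lists the lowest score was 830, which corresponds to an IDR of 0.01. The conservative list of 999 regions was the main list. The ranked list of the true replicates holds 1086 regions with that score or a higher one, and 87 of them are not in the conservative list. The signal of each replicate at a peak comes from that ranked list, where the replicates' order is not named, and is given as mean ± SD over 2 replicates. Each pooled signal is the authors' value and has no error of its own. No replicate signals were identical between replicates at any of the 979 nuclear peaks (0 identical pairs).

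Peaks were annotated with Ensembl release 115 on WBcel235, whose chromosome lengths hold all the peaks (0 regions lie outside them). Mitochondrial peaks were left out of the comparisons. A summit was placed in a promoter if it lay between 1000 bp upstream and 200 bp downstream of the 5' end of any transcript, and otherwise in an exon, an intron or intergenic sequence, in that order. A gene was called bound if its own promoter window held a summit. Replicate lists were compared by overlap of at least 1 bp and 1000 random placements, locations by 10000 random placements on the same chromosome, and the X share by 10000 placements over the genome. Gene lists were tested by Fisher's exact test, two-sided, against 19973 protein-coding genes, with Benjamini-Hochberg adjustment over 31 lists, and gene classes against all nuclear genes. Overlapping promoters make genes not fully independent. The 6-mers in 100 bp windows were compared with a flank centred 300 bp away on a random side, by a paired sign test. GC content was compared by permutation of signs.

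The rule for named genes was fixed before the data were examined. It takes the gene with the nearest 5' end within 1000 bp for each of the 25 strongest conservative peaks, up to 4 members with the highest signal in each list that passed, every member of the list named CoREST and LSD1 factors, and hmg-20. The lists, tests and the following alternatives were fixed at the same time. These were the list of each replicate alone, the other series list, an IDR of 0.01, other promoter windows, protein-coding 5' ends, the nearest gene, circular shifts of the summits, other overlap rules, all ranked regions, Pearson's r, and other windows, flanks and a dinucleotide shuffle for 6-mers. Added after the data were seen were an IDR of 0.05, a global IDR of 0.001, summits within 256 bp of a stronger one left out, summits in tRNA, snoRNA and snRNA windows left out, 5' ends without piRNA genes, and all ranked regions past the threshold, with the 87 that the authors left out.

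The steps were tested on simulated data. In the promoter share step, with 979 summits, 0 of 20 sets of uniform summits were called, and a simulated share of 68.8% was recovered as 67.5%. In the gene list step, with 19973 genes, lists of 200 genes bound at 5 times the usual rate were recovered in 20 of 20 simulations and lists of 40 genes in 9 of 20. In the 6-mer step, over 2080 6-mers, 10 of 10 planted 6-mers were recovered and 0 were called between flanks. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.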

Results

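The data are chromatin immunoprecipitation sequencing of HMG-20 in Caenorhabditis elegans. HMG-20 is a protein with a high-mobility-group box, a DNA-binding domain. The worms carried a TY1, EGFP and 3xFLAG tag inserted by CRISPR at the hmg-20 gene on chromosome I, and chromatin was precipitated with an antibody against GFP. Whole young adults were taken at 64 hours. There was 1 group with 2 biological replicates, so the comparisons are between replicates and between the bound regions and the genome. The deposited lists give no read totals, so the depth behind each peak is unknown. Positions are on the ce11 assembly.

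The conservative list derived from both replicates held 999 regions, and 979 of these were on the nuclear chromosomes. The strongest nuclear peak stood 27 bp upstream of the snoRNA gene ZK994.7 (WBGene00044958; chromosome V, 8500445 to 8500659), with a pooled signal of 422.8 and a replicate signal of 204.8 ± 11.4 (SD, n = 2). The next was 285 bp upstream of rpl-3 (WBGene00004414; chromosome III, 3867484 to 3867668), which encodes a large-subunit ribosomal protein, with a pooled signal of 396.4 and a replicate signal of 201.9 ± 1.26 (SD, n = 2). A peak at 4749993 to 4750153 of chromosome IV lay between rpl-20 and Y17G9B.5, 287 bp upstream of the first and 175 bp upstream of the second, with a replicate signal of 178.3 ± 25.6 (SD, n = 2). A further peak lay 352 bp upstream of rpl-15 (chromosome IV, 654843 to 655006), with a replicate signal of 157.6 ± 5.44 (SD, n = 2). The nuclear peaks had a median signal of 76.8. Of the 25 strongest peaks, 18 lay on the mitochondrial genome and 7 on nuclear chromosomes.

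The comparison between replicates asked how far the bound regions recur. Of the 498 nuclear peaks of replicate 1, 267 overlapped a peak of replicate 2 by at least 1 bp, or 53.6% (95% exact interval 49.1 to 58.1). Of the 448 nuclear peaks of replicate 2, 268 overlapped a peak of replicate 1, or 59.8% (55.1 to 64.4). Of the 979 nuclear conservative peaks, 433 overlapped a peak of replicate 1, 405 a peak of replicate 2 and 271 both, and 412 (42.1%) overlapped neither. Random placement of the replicate 2 peaks on their own chromosomes gave 0.208% on average and at most 1.00% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The signal at the 979 nuclear peaks correlated between replicates with a Spearman rho of 0.432, against 0.233 over all 59096 ranked nuclear regions, and Pearson's r on log2 values was 0.665 at the peaks. Peaks are not independent replicates. The list holds only regions past a threshold on agreement between these same 2 replicates, so agreement at the peaks partly follows from that choice. The replicate signals were over 2 times apart at 52 peaks, or 5.31%.

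**Figure D1:**
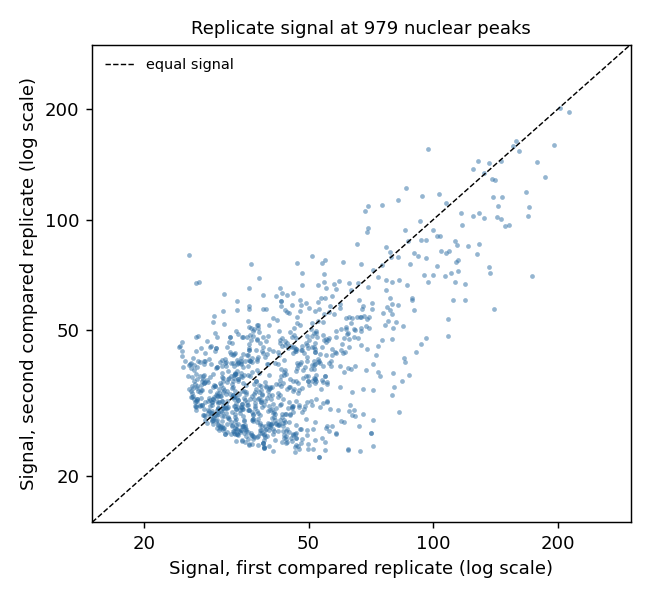
Signal of the authors' peak caller in the first (x axis) and second (y axis) compared replicate at the 979 nuclear peaks, on log scales without a stated unit. Each point is a peak, the dashed line marks equal signal, and the medians were 40.6 and 36.9.

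HMG-20 summits were concentrated at promoters, defined as 1000 bp upstream to 200 bp downstream of an annotated transcript's 5' end. Promoters held 753 of the 979 summits, or 76.9% (95% exact interval 74.1 to 79.5), against 38.2% in random placement, a ratio of 2.02. Exons held 7.66%, introns 4.90% and intergenic sequence 10.5%, against 20.8%, 24.4% and 16.6% at random. Each of the 4 shares differed from random placement (two-sided permutation p = 2e-04, the smallest that 10000 placements can give). The intergenic share was not told apart from random placement without replicate 2 (13.5%, permutation p = 0.062), at an IDR of 0.05 (15.5%, p = 0.185) and without small RNA windows (14.99%, p = 0.449). Among all 1066 nuclear regions past the threshold, which include 87 that the authors left out of the conservative list, 16.6% were intergenic, as at random (permutation p = 1), and 71.5% were in promoters. Of those 87 regions, 74 were intergenic. The set at an IDR of 0.05 was taken from the ranked list and also includes them, so its intergenic share does not show the looser threshold alone. With the 5' ends of protein-coding genes alone, 484 summits, or 49.4%, were in promoters, against 25.9% at random. Exons then held 21.5% against 24.3% (permutation p = 0.0424), introns 10.1% against 27.9% and intergenic sequence 18.999% against 21.9% (permutation p = 0.0288), so the low exon share depends on which 5' ends are used.

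**Figure D2:**
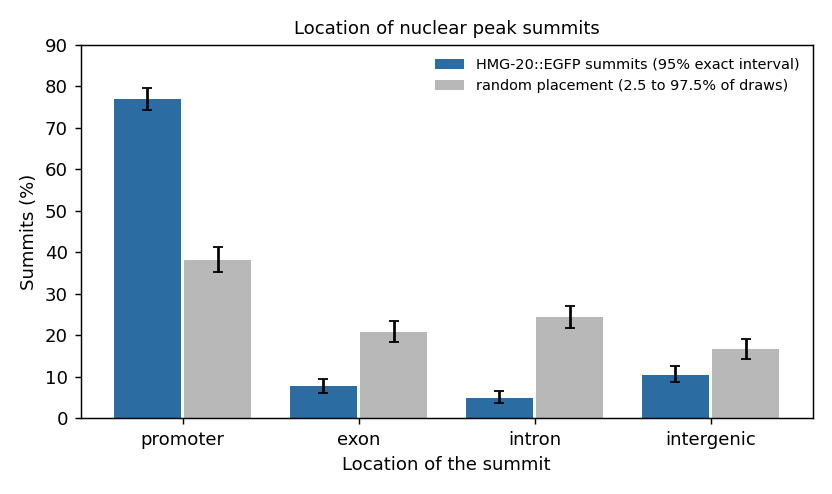
Percent of the 979 nuclear summits (y axis) in promoters, exons, introns and intergenic sequence (x axis), with 95% exact intervals, beside the mean of 10000 random placements and the range of the middle 95% of them. Promoters hold 76.9% of summits against 38.2% at random.

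Pooled over all ranks below the authors' threshold, regions showed no such concentration. Of 58030 nuclear regions below it, 22312 had a promoter summit, or 38.4%, which is near the 38.2% of random placement. The odds of a promoter summit were 5.33 times higher above the threshold (95% interval 4.59 to 6.22, Fisher's exact test, two-sided p = 2.51e-130). The regions above the threshold are the 979 conservative peaks, without the 87 left out by the authors. With those the odds ratio was 4.01 (3.505 to 4.603). It was 2.80 at an IDR of 0.05, a set that also includes the 87, and 3.27 without small RNA windows.

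The peaks were spread over all 6 nuclear chromosomes, with a higher share on X and in the middle of the autosomes. X held 210 summits, or 21.5%, against 17.7% in random placement (two-sided permutation p = 0.0018). On X, 101 summits lay in the promoter window of a tRNA gene, against 13 to 19 on each autosome, and X holds 276 of the 612 annotated tRNA genes. Without the summits in tRNA, snoRNA and snRNA windows the X share was 15.3%, which was not told apart from random placement (permutation p = 0.105). Of 769 autosomal summits, 450 fell in the middle 50% of the chromosome by length, or 58.5% against 50% at random (two-sided permutation p = 2e-04, the smallest possible).

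Among the gene classes, genes of tRNAs, snoRNAs and snRNAs were bound most often. A promoter summit was found at 218 of 612 tRNA genes (35.6%), 84 of 346 snoRNA genes (24.3%) and 32 of 129 snRNA genes (24.8%). The odds ratios against all other genes were 21.4, 11.2 and 11.1, with Benjamini-Hochberg adjusted exact p of 1.07e-173, 5.32e-51 and 2.56e-20 by Fisher's exact test over the annotated gene classes. The snRNA odds ratio was 6.96 without replicate 1 and 6.804 at a global IDR of 0.001. Other ncRNA genes were bound at 322 of 7764 (4.15%, odds ratio 1.55, adjusted exact p = 1.47e-10), against 2.71% of all other genes. Those other genes include the 15363 piRNA genes, bound at 0.430%, which lower that share. Whether the ncRNA excess holds without piRNA genes in the background was not tested. Promoter summits were fewer at piRNA genes, with 66 of 15363 (odds ratio 0.099, adjusted exact p = 4.72e-148; odds ratio 0.063 without replicate 1, 0.0647 at a global IDR of 0.001 and 0.0485 with a promoter of 500 bp on each side), and at pseudogenes, with 21 of 2128 (odds ratio 0.318, adjusted exact p = 1.25e-09). Protein-coding genes were bound at 625 of 19973 (3.13%, odds ratio 1.12) and did not pass the test (adjusted exact p = 0.0735), with piRNA genes in the background here too. The classes miRNA (7 of 261), lincRNA (5 of 194), antisense RNA (2 of 100) and rRNA (0 of 20) did not pass either. Neighbouring genes can share a summit, and the strongest summits of the 218 tRNA genes were 181 different ones. Those of the 66 piRNA genes were 27 different ones. The exact p of a class counts such genes as independent, so the piRNA p is too small by an unknown amount. Among named peaks, sls-2.1 (chromosome II, 5844733 to 5844932), a spliced leader RNA gene, had a replicate signal of 139.8 ± 44.1 (SD, n = 2), and rpr-1, an ncRNA gene on chromosome I, 127.6 ± 17.1 (SD, n = 2). These genes were chosen after their values were seen.

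Distances from the summit to the nearest 5' end are given by class, without a test between classes. Where the nearest 5' end was that of a tRNA gene, the median summit lay 7.5 bp downstream of it, and 96.3% of 164 such summits were within 100 bp. Near snoRNA and snRNA genes, 87.9% of 66 and 93.1% of 29 summits were within 100 bp. For protein-coding genes 19.2% of 530 summits were within 100 bp, and the summit had a median position of -117.5 bp and quartiles of -296.8 and 277.8 bp, where negative is upstream.

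**Figure D3:**
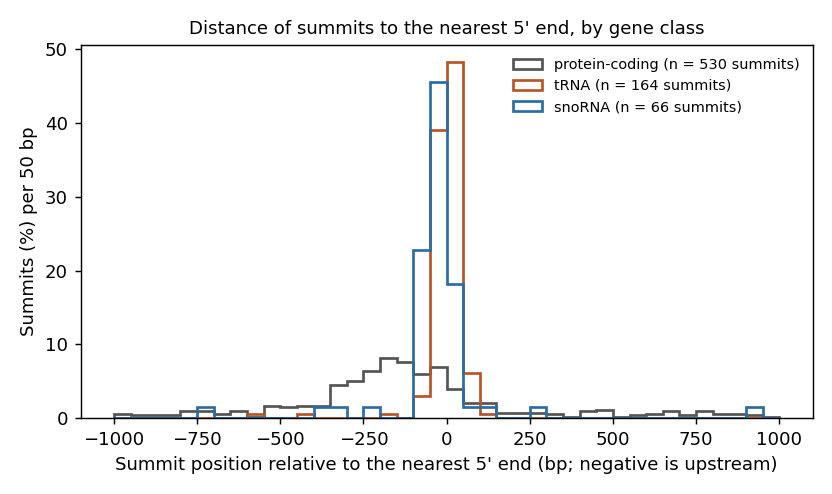
Position of summits relative to the nearest annotated 5' end (x axis, bp, negative is upstream) as percent of summits per bin (y axis), for protein-coding, tRNA and snoRNA genes, with summits beyond 1000 bp not drawn. Summits near tRNA genes sit around the 5' end and those near protein-coding genes are spread on both sides with a median of -117.5 bp.

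Among protein-coding genes, those for ribosomal proteins were bound most often of the 31 gene lists tested, of which 7 were bound more often and 2 less often than other genes. A promoter summit was found at 27 of 82 ribosomal protein genes (32.9%), against 3.01% of other protein-coding genes (odds ratio 15.8, 95% interval 9.53 to 25.7, Fisher's exact test with Benjamini-Hochberg adjusted p = 2.91e-19). Besides rpl-3, rpl-20 and rpl-15, rpl-35 on chromosome III had a replicate signal of 131.0 ± 21.9 (SD, n = 2). Genes of translation factors were bound at 7 of 43 (odds ratio 6.08, adjusted exact p = 0.00178). They included ifet-1, a binding partner of the cap-binding protein, with 126.4 ± 41.1, eif-3.C with 92.2 ± 5.67, the elongation factor gene eef-2 with 60.3 ± 13.7 and eif-2Bgamma with 44.6 ± 23.2 (SD, n = 2). The ifet-1 summit lay 503 bp upstream of that gene and 4 bp from the 5' end of the ncRNA gene F56F3.11, and is also the one assigned to rps-1. The eif-2Bgamma summit was nearest to the 5' end of an snRNA gene. The translation factor list did not pass without replicate 1 or at a global IDR of 0.001 (adjusted exact p = 0.114 and 0.0962), and its odds ratio was 11.1 without replicate 2.

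Genes in the list of heat shock proteins and chaperones were bound at 12 of 67 (odds ratio 6.87, adjusted exact p = 1.02e-05). The chaperonin gene cct-8 had a replicate signal of 136.7 ± 11.7, hsp-90 of 88.6 ± 25.7, hsp-60 of 85.99 ± 8.76 and dnj-19 of 70.4 ± 16.9 (SD, n = 2). The hsp-90 summit lay 399 bp upstream of the 5' end of 1 of its transcripts and inside the gene. The cct-8 summit is shared with Y55F3AR.2 and the dnj-19 summit with nhr-47, and the hsp-60 summit lay nearer to the 5' end of another protein-coding transcript. When only the gene with the nearest 5' end was assigned to a summit, this list did not pass (odds ratio 1.22, adjusted exact p = 0.826).

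Other chromatin regulators were bound at 9 of 65 genes (odds ratio 5.03, adjusted exact p = 0.00141; odds ratio 7.76 without replicate 1 and 8.31 at a global IDR of 0.001). Among the members with the highest signal, lin-53, lin-9 and lin-54 encode subunits of the worm DREAM complex. Their replicate signals were 96.04 ± 4.24 at lin-53, 87.3 ± 0.562 at lin-9 and 65.4 ± 20.7 at lin-54 (SD, n = 2). The lin-54 summit, 357 bp upstream of that gene, is also the one assigned to the ribosomal protein gene rpl-12. The methyltransferase gene set-16 had 85.4 ± 6.17 (SD, n = 2). The list named CoREST and LSD1 factors has 14 genes, and its members hop-1 and sel-12 encode presenilins rather than such factors. Of the 14 genes, hmg-20 was the 1 with a promoter summit (7.14%, odds ratio 2.38, adjusted exact p = 0.557), and amx-1, hda-1, hda-2, hda-3, hop-1, lsd-1, rcor-1, sel-12, spr-1, spr-2, spr-3, spr-4 and spr-5 had none. The hmg-20 peak (WBGene00012209; chromosome I, 12534468 to 12534723) lay 718 bp upstream of the gene, which spans 12535314 to 12537671 on the plus strand, with a replicate signal of 34.4 ± 0.314 (SD, n = 2). It was in neither replicate's own thresholded list, and was lost at a global IDR of 0.001 and with a promoter of 500 bp on each side.

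The mitochondrial respiratory chain, encoded in the nucleus, was represented by 9 of 67 genes (odds ratio 4.86, adjusted exact p = 0.00143), with cox-5A at 117.2 ± 22.4, atp-1 at 54.02 ± 21.1, cox-5B at 46.1 ± 5.18 and cox-6A at 37.6 ± 4.55 (SD, n = 2). This list did not pass without replicate 1, without replicate 2 or at a global IDR of 0.001 (adjusted exact p = 0.263, 0.102 and 0.258), and its odds ratio was 2.97 without replicate 1. The cox-6A summit was nearest to the 5' end of an snRNA gene. Cell cycle and DNA replication genes were bound at 10 of 100 (odds ratio 3.48, adjusted exact p = 0.00512), with cdc-48.1 at 126.2 ± 24.2, rpa-2 at 104.3 ± 46.2, the sliding clamp gene pcn-1 at 71.7 ± 2.47 and knl-3 at 64.0 ± 17.6 (SD, n = 2), and did not pass without replicate 1, with a promoter of 500 bp on each side, at a global IDR of 0.001 or with the nearest gene alone (adjusted exact p = 0.0901, 0.0528, 0.0698 and 0.211; the last with an odds ratio of 2.09). The knl-3 summit was nearer to another protein-coding transcript and the rpa-2 summit to a lincRNA gene. Splicing factor genes were bound at 6 of 62 (odds ratio 3.34, adjusted exact p = 0.044), with mog-4 at 122.6 ± 37.7, rsr-1 at 78.4 ± 42.8, snr-4 at 62.7 ± 11.7 and prp-19 at 58.0 ± 4.48 (SD, n = 2), and did not pass with a promoter of 500 bp on each side, one of 2000 bp upstream, the nearest gene alone or small RNA windows left out (adjusted exact p = 0.184, 0.108, 0.382 and 0.063). Its odds ratio was 5.60 without replicate 1 and 6.11 without replicate 2, and 5.998 at a global IDR of 0.001. It was 2.60 with a promoter of 500 bp on each side, 2.41 with 2000 bp upstream and 2.02 at the lowest. The snr-4 summit was nearest to the 5' end of an snRNA gene, and the prp-19 summit is shared with the cell cycle gene emb-1.

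Genes of sensory receptors and of innate immunity were bound less often than other protein-coding genes. Chemoreceptor genes had a promoter summit at 7 of 1294 (odds ratio 0.159, adjusted exact p = 7.68e-10), with sre-23 at 89.2 ± 27.7, sri-5 at 78.4 ± 42.8, srh-16 at 66.9 ± 20.3 and srd-44 at 43.1 ± 5.07 (SD, n = 2). Without small RNA windows the odds ratio was 0.0818. The sre-23 summit was nearest to the 5' end of a snoRNA gene and the srd-44 summit to that of a tRNA gene. The sri-5 summit is the one assigned to rsr-1, which lies on the other side of it. Innate immunity and C-type lectin genes were bound at 2 of 348 (odds ratio 0.176, adjusted exact p = 0.0101), with clec-126 at 37.3 ± 10.4 and clec-57 at 34.6 ± 6.68 (SD, n = 2). The clec-126 summit was nearest to the 5' end of a tRNA gene and the clec-57 summit to that of an snRNA gene, and the latter is shared with the chemoreceptor gene srz-97. No gene of the list had a summit without replicate 1, without replicate 2 or without small RNA windows (odds ratio 0). The innate immunity list did not pass at a global IDR of 0.001 (adjusted exact p = 0.0572). Neither list passed when the summits were shifted together along each chromosome (adjusted permutation p = 0.248 and 1). Those shifts expected 13.3 chemoreceptor and 3.77 innate immunity genes. They compare a list with shifted positions, so they do not decide whether it is bound less often than other protein-coding genes.

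The other lists did not pass the test. With the summits shifted along each chromosome, the vitellogenin list and the germline and oocyte list did (adjusted permutation p = 0.024 and 0.0241). The shifts do not compare a list with other protein-coding genes. Promoter summits were found at 2 of 7 vitellogenin and yolk receptor genes (adjusted exact p = 0.0573), 5 of 69 germline and oocyte genes, 1 of 172 cuticle collagens, 1 of 146 neuropeptides, 2 of 18 heterochronic and microRNA pathway genes, 4 of 275 nuclear hormone receptors, 2 of 21 vacuolar ATPase subunits, 4 of 251 detoxification genes, 2 of 31 proteasome subunits and 4 of 72 histones. The remaining counts were 1 of 101 homeobox factors, 2 spermatogenesis genes (1.79%), 0 of 39 epidermis genes, 1 of 63 signalling genes, 1 of 48 GATA, forkhead and T-box factors and 1 of 42 basic helix-loop-helix factors. Tissue lists gave 1 of 54 intestine genes, 1 of 49 meiosis genes, 1 of 59 muscle genes, 1 of 34 pharynx genes and 2 of 68 synaptic genes.

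**Figure D4:**
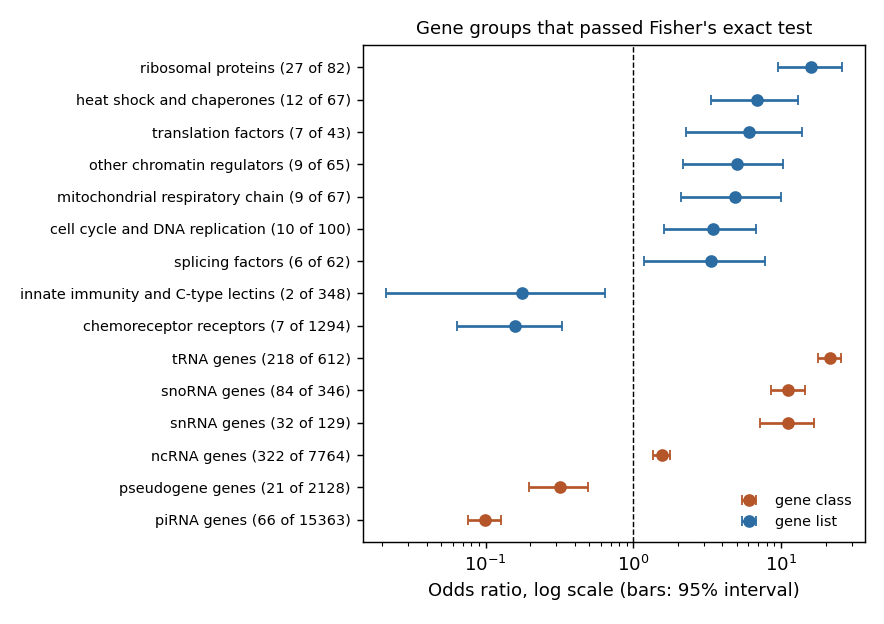
Odds ratio of a promoter summit (x axis, log scale) with 95% intervals for the 6 gene classes and 9 gene lists that passed Fisher's exact test (y axis, with the bound and total genes). tRNA genes have the highest odds ratio, 21.4, and ribosomal protein genes the highest of the lists, 15.8.

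Sequence under the summits was rich in G and C. The 100 bp around the 979 summits held 48.9% ± 7.82 GC (SD over summits) against 35.9% ± 8.86 in flanks 300 bp away (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Of 2080 6-mers, 539 were present more often at summits and 349 more often in flanks (exact paired sign test, Benjamini-Hochberg adjusted). The 6-mer ACGCGC was in 11.5% of summit windows and 0.817% of flanks (adjusted exact p = 6.23e-23), GCGCCA in 12.4% and 1.63% (1.20e-19), and AACGCG in 10.8% and 1.23% (2.92e-18). GAGCGC was in 11.5% and 1.53% (1.16e-17), and GCGCAC in 11.3% and 1.53% (1.43e-17). Against sequence shuffled with its dinucleotides kept, 133 6-mers were more frequent at summits, and ACGCGC did not pass (adjusted exact p = 0.0739). The difference between summits and reference, in percent of windows, fell from 10.7 to 3.17 for ACGCGC, from 10.7 to 8.58 for GCGCCA, from 9.60 to 3.68 for AACGCG (adjusted exact p = 0.0346), from 10.01 to 4.70 for GAGCGC and from 9.81 to 5.62 for GCGCAC. At an IDR of 0.05 these differences from flanks were 6.96, 7.37, 6.33, 6.49 and 6.12.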

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

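All tests in this part were chosen after the result was seen, except the test of tRNA genes with identical copies, whose prediction was written first. No biological explanation was tested, since the design has 1 group.

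Signal outside the nuclear comparisons was found on the mitochondrial genome, where the conservative list has 20 peaks that cover 32.5% of its 13794 bp. Their median signal was 713.8 and the lowest 240.1, against at most 422.8 on nuclear chromosomes. The rule for named genes takes 18 of them. The strongest, with a replicate signal of 2160 ± 180.3 (SD, n = 2), lay 84 bp upstream of the tRNA gene WBGene00014473, and COX3 had 462.9 ± 20.1 and ND1 331.4 ± 7.12 (SD, n = 2). Protein-coding genes without a symbol in the annotation were WBGene00000829, WBGene00010960, WBGene00010961, WBGene00010964 and WBGene00010967, with pooled signals of 447.8 to 3221. The others were the rRNA gene WBGene00014454 and the tRNA genes WBGene00014458, WBGene00014465, WBGene00014467 and WBGene00014471. Whether the mitochondrial signal reflects binding of HMG-20 stays open, since the control library was not analysed here.

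In the ranked list, 87 regions past the threshold are absent from the conservative list. Of these, 74 were intergenic and 24 on X, and the highest signal was 2470 at 15810954 to 15811190 of chromosome X.

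The share of summits on X, 21.5%, was above the 17.7% of random placement. X holding more tRNA genes is a candidate explanation, since outside the tRNA, snoRNA and snRNA windows the share was 15.3%, below the upper random bound of 20.4%. A higher share of ranked regions on X at any rank stays open. Over all regions, 20.9% of those below the threshold lay on X, not told apart from the peaks (Fisher's exact test, p = 0.663), whereas outside the windows the share was 20.8% below the threshold, above that of the peaks (p = 0.000311). tRNA genes on X also had a summit more often, at 123 of 276 (44.6%) against 95 of 336 on autosomes (28.3%), a difference that was not tested.

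tRNA genes had a summit at 35.6%. Reads shared between identical genes are argued against as the whole cause, since tRNA genes found once in the genome had a summit at 37 of 140, or 26.4% (95% exact interval 19.3 to 34.5), against 38.3% of genes found more than once (Fisher's exact test, p = 0.0118). Sharing between near-identical genes cannot be told apart from binding. The genes found once with no other within 3 mismatches and no tRNA gene nearby number 46, and 5 had a summit, or 10.9% (3.62 to 23.6). That interval lies above the 2.52% of all other genes, but its lower bound missed the level set for arguing against sharing. Signal at strongly transcribed genes of any polymerase may contribute, since ribosomal protein genes had a summit at 32.9%. Annotated rRNA genes had a summit at 0 of 20, however, and transcription was not measured here. The control library was not analysed here either, so a part played by strong transcription stays open.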

How the results depend on the processing

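The alternatives with an IDR of 0.05, a global IDR of 0.001, close summits left out, small RNA windows left out, no piRNA 5' ends and the authors' 87 omitted regions put back were chosen after seeing the data. The IDR of 0.01 moved nothing, since the deposited lists already stop there, and says nothing about stability. The promoter share, its contrast above and below the threshold, the middle share of autosomes and the replicate overlap kept their direction and passed under every other alternative run for them, the contrast with odds ratios down to 2.80. All 6 gene classes that passed kept their direction and passed under 7 other alternatives, each with piRNA genes in the background. Of the lists, ribosomal proteins (odds ratio 11.95 to 22.9) and other chromatin regulators (3.62 to 8.31) passed under all 10 other gene assignment and peak list alternatives. Both also passed under the circular shift, which does not compare a list with other protein-coding genes. Without the summits in tRNA, snoRNA and snRNA windows the X share was 15.3%, no longer told apart from random placement, and 337 6-mers passed. Fewer summits were tested there. Single replicates gave 475 to 519 peaks, 4 to 6 lists bound more often and 317 to 329 6-mers, with fewer peaks tested. An IDR of 0.05 gave 1932 peaks, taken from the ranked list and so with the authors' 87 omitted regions. A global IDR of 0.001 gave 428 peaks, 4 lists bound more often, 1 bound less often and 326 6-mers, again from fewer peaks. The nearest gene alone gave 4 lists bound more often, and the cause was not tested. Circular shifts gave 9 lists bound more often and 0 bound less often. These compare a list with shifted positions, so every list also gains from the general concentration of summits at promoters. For ribosomal proteins the shifts expected 0.961 of 82 genes (observed 27), whereas 3.01% of other protein-coding genes were bound. Shuffled summit sequence in place of the genomic flank gave 133 6-mers, and the cause was not tested. The replicate correlation was 0.233 over all ranked regions and 0.665 as Pearson's r on log2 values, and the cause was not tested. Of 48 nuclear genes named by signal, 42 and 43 kept a promoter summit in replicate 2 and replicate 1 alone, and hmg-20, cox-5B, clec-126 and clec-57 kept it in neither. The lists give no read depth, so its limit on weak regions is unknown. No paired analysis was possible because the series has 1 group.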

Other observations

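The tests in this part were chosen after the result was seen, and the sequence searched for was taken from textbook knowledge.

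Among the 25 strongest nuclear peaks, those away from promoters were all on X. Of the 25 strongest nuclear peaks, 10 were on X, and 8 of these lay in no promoter window. They included 6296454 to 6296670, in an intron, with a replicate signal of 161.5 ± 3.55, 11094050 to 11094329, intergenic, with 157.0 ± 1.94, and 4209193 to 4209371, intergenic, with 139.5 ± 4.11 (SD, n = 2). Over all nuclear summits, promoters held 161 of 210 on X and 753 of 979 in total, while 33 of the 103 intergenic summits were on X. The 87 regions left out of the conservative list had a median signal of 122.7, with 74 intergenic and 24 on X.

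The 12 bp consensus TCGCGCAGGGAG is known from the X sites that recruit the worm dosage compensation complex. It was found within 100 bp of the summit, with at most 1 mismatch, at 12 of 210 X summits (5.71%) and 0 of 769 autosomal summits, which allows a share of up to 0.390% (Fisher's exact test, two-sided p = 7.37e-09). With 2 mismatches allowed the counts were 20 and 9. The 12 summits had a median signal of 276.6, against 76.8 at other X summits, and 10 of them were among the 12 strongest nuclear X peaks. Chance matches to a 12-mer of this base composition are argued against, since 0 of 1000 permutations of the consensus matched as many X summits and the highest matched 8. The permutations keep the bases of the consensus but not its dinucleotides, so chance matches from dinucleotide content were not tested. In the genome, X held 32 matches and the autosomes 37, although X is 17.7% of the nuclear sequence, so matches are denser on X. That density is argued against as the whole cause. Of the 32 matches on X, 16 (50%) had a summit within 100 bp, and of the 37 on autosomes 0 did (Fisher's exact test, p = 3.14e-07), although matches can share a summit. HMG-20 may therefore lie at dosage compensation sites, as a hypothesis from the data it was tested on. Signal at such sites in any precipitation stays open, since the control library was not analysed here.

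At tRNA genes the summits carried GTTCGA, part of the internal promoter of tRNA genes, in 36.2% of windows, against 5.04% of windows elsewhere. Of the summits nearest a tRNA gene, 96.3% lay within 100 bp of its 5' end, so the windows can hold part of the gene itself. The difference therefore cannot show a sequence preference of HMG-20.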
